A study of Mus musculus with 33 samples.

How the data were processed

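RNA from 33 mouse samples was labelled with biotin and hybridized to single-colour Affymetrix arrays, 1 sample per array, with 6 µg of total RNA as starting material, per the labels' protocols. Of these, 19 were tumors and 14 were cell cultures. The deposited table held an intensity, the brightness of a set of oligonucleotide probes on a linear scale, for each of 45101 probe sets on each array. The deposited intensities ran from 0.103 to 24431.7, and the median of an array lay between 61.1 and 61.3. When each array's values were sorted, 76.4% of the ranks held values within 1% of each other on all 33 arrays, as they do after quantile normalization over all arrays. The probe set summary and the normalization that the authors used are not given in the sources used here; the submitters' processing notes name limma, without its role or version. No further normalization was applied, since the deposited intensities already shared 1 distribution. Such values carry relative changes, and a shift of all genes in the same direction would not be seen in them. No pair of arrays held identical values, and 0 columns were left unused. For arrays, the number of samples limits the precision.

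Samples were grouped by their titles. The tumor lines called iKras1 to iKras5 came from mice with a doxycycline-dependent oncogenic Kras transgene, the rtTA activator, a p48-driven Cre recombinase and 1 conditional p53 allele. The control lines called LSL-Kras1 and LSL-Kras2 came, per the series' design text, from tumors driven by a Cre-activated mutant Kras allele that does not need doxycycline (LSL, lox-stop-lox). Their genotype labels repeat the genotype of the iKras lines, which disagrees with that text; the design text was followed. The sample titled as LSL-Kras2 without doxycycline has a source label that also says off, while its treatment label and treatment protocol say on. It was placed in the group without doxycycline by its title. The tests of genes with LSL cultures were repeated without that line, while the tests and intervals of gene lists were not. The labels number the tumors of a line but do not say whether each came from a separate animal, so part of the spread between tumors of 1 line could be technical. In the cultures, the replicate was the line, with 1 culture per line and condition.

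Probe sets were named through a table of the platform's annotation. Of the probe sets, 34945 had a single gene symbol, 932 had several and 9211 had none; 64 were controls, which were not used as genes and in part also count among those with several symbols or none. Genes were tested on 1 probe set each, the singly named probe set with the highest mean over all arrays, which gave 18193 genes; 9010 of them had several probe sets. Kras, Hras, Gapdh, Hmgcr, Ldlr and Dhcr24 had no singly named probe set and are not analysed here. No genome build or coordinates were used, because none is given with the table.

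All tests used log2(intensity + 1), so that a change of a dim gene is understated; 1.42% of the values were below 1. Linear models were fitted to all 18193 genes with limma (lmFit and eBayes), with line as a fixed block, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Tumors were fitted apart from cultures. The iKras and LSL cultures shared 1 fit with a separate doxycycline effect for each kind of line, from which the difference of the 2 effects was tested. A fit over the 29 iKras arrays, with line within setting as a block, tested whether the effect differed between tumors and cultures, and another tested tumors against cultures on doxycycline. Line is part of the design because each line gave samples with and without doxycycline. The deviations from group means bore this out: each of the 5 lines correlated best with itself between the doxycycline groups of the cultures (r across genes from 0.487 to 0.735) and of the tumors (r from 0.284 to 0.607).

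Before the data were examined, 49 gene lists with at least 3 measured members were fixed, 34 of pathways and 15 of cell type markers. They were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 49 lists; camera with an estimated correlation and fry, which tests whether the genes of a list moved on balance in 1 direction, were alternatives. Counts of list members were taken over all genes tested and, separately, adjusted over the list alone. An exact two-sided permutation test of each list's mean on the tumor arrays, exchanging doxycycline labels within lines, was added after the data had been seen; it has 3888 permutations and a smallest possible p of 0.000257. Both the list tests for the LSL cultures and those for the differences between settings were added as well. Ratios of the 3'-end to the 5'-end control probe sets of Gapdh and beta-actin, signs of RNA quality, were compared between doxycycline groups by an exact two-sided permutation test over all arrays of a setting, adjusted over the 6 tests. The same test with labels exchanged within lines was added after the data had been seen.

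The genes named below were chosen by a rule fixed before the data were examined. For the tumor and the culture comparisons these were the 10 largest rises and the 10 largest falls among called genes with the same sign in every iKras line, a fixed set of Ras, glucose metabolism and MAPK feedback genes whatever their values, and up to 4 members with the lowest p of each list spoken of. For the other comparisons they were the 5 largest changes in each direction among called genes; the fixed set is also given for the LSL cultures and their difference from iKras cultures. A gene named outside this rule is marked as such.

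The fits were tested on simulated data built from these samples, with 18193 genes in each fit, of which 67, 67 and 66 were changed by 0.5, 1 and 2 log2 units. In the tumor comparison 25.4%, 76.1% and 87.9% of the genes of these 3 sizes were recovered. In the iKras cultures the recovered shares were 25.4%, 62.7% and 74.2%. In the LSL cultures, and in the difference between iKras and LSL responses, they were 0%, 17.9% and 51.5%. For the difference between tumor and culture responses they were 5.97%, 53.7% and 65.2%, and for tumors against cultures 29.9%, 52.2% and 87.9%. Besides these genes, those of the lysosome and autophagy list were lowered by 0.5 log2 units, and these shares do not count them. Noise was drawn independently for each gene and array, so the shares may differ for real arrays.

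The alternatives fixed before the data were examined were an added offset of 32 before the logarithm, removal of the 40% dimmest genes, the mean of a gene's probe sets or every probe set as a row, centring or renewed quantile normalization of the arrays, eBayes with trend and robust options, array weights, line left out or as a random block, tumors averaged per line, 1 fit of all arrays, iKras cultures alone, a host cell marker score (macrophage, fibroblast and endothelial lists) as a covariate, and each line left out in turn. An acinar marker score and the beta-actin ratio as covariates, each tumor left out in turn and the permutation of list means were added after the data had been seen. Analyses were run in R 4.3.3 with limma 3.58.1 and in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.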

Results

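Gene expression was profiled in pancreatic tumor lines whose oncogenic Kras transgene is switched on by doxycycline (dox) and off by its withdrawal. The 5 lines, iKras1 to iKras5, were injected into the pancreas of nude mice, which were kept on dox for 2 weeks; part of the animals were then taken off dox for 24 h. Tumors with more than 75% cellularity were taken, which gave 10 tumors on dox and 9 off dox, with 2 tumors per line and condition except for a single tumor of iKras1 off dox. The same 5 lines were grown in culture with dox or without it for 24 h (5 arrays each). Cultures of 2 control lines, whose mutant Kras allele does not depend on dox (LSL-Kras1 and LSL-Kras2), were treated in the same way (2 arrays each). The series' title names the hexosamine pathway and the non-oxidative pentose phosphate pathway, so those lists and glycolysis were chosen by the study on these samples, and their direction here is not independent evidence. Changes are given as off minus on dox on the log2(intensity + 1) scale with their standard error (SE), and adjusted p-values are from limma with Benjamini-Hochberg adjustment unless another test is named.

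The first comparison asked which transcripts changed in established tumors after dox withdrawal. No tumors of the LSL lines were profiled, so loss of the transgene cannot be told from doxycycline itself in tumors. After 24 h off dox, 8 of 19 output genes of the MAPK cascade fell, among them its feedback inhibitors Dusp6, Spry2 and Spry4, as did 4 of 6 ligands of the EGF receptor and 16 of 20 genes of cholesterol synthesis, while the pro-death genes Bmf and Bcl2l11 rose. These 3 lists had adjusted p = 0.224 with an estimated correlation. Dusp6, the phosphatase that inactivates ERK, stood at 12.05 ± 0.22 (SD, n = 10) in tumors on dox and at 10.94 ± 0.48 (SD, n = 9) off dox. That was a fall of 1.10 ± 0.15 (SE) in all 5 lines (adjusted p = 0.00106). Of 18193 genes, 579 rose and 584 fell, 1095 of them with the same sign in every line; 50 rose and 94 fell at least 2-fold.

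Among the largest falls with the same sign in all 5 lines, F3 (tissue factor, which starts coagulation) fell by 2.06 ± 0.27 (adjusted p = 0.000891). Gjb1, a gap junction connexin, fell by 2.06 ± 0.25. Agr2, a protein of the endoplasmic reticulum of secretory epithelia, fell by 2.05 ± 0.49, and Ivl, the envelope protein involucrin, fell by 1.78 ± 0.37. Ereg, the EGF receptor ligand epiregulin, fell by 1.80 ± 0.34, and Dusp5, a nuclear ERK phosphatase, fell by 1.79 ± 0.39. Tmem190, Tmem163, Tcf23 and Ugt2a3 fell by 1.81 to 1.91, of which Ugt2a3 was dim in both groups, at 4.03 ± 1.29 (SD, n = 10) on dox and 2.01 ± 0.67 (SD, n = 9) off dox. Bco2, a carotenoid-cleaving oxygenase, rose by 2.23 ± 0.41 (adjusted p = 0.00545) from a dim mean of 3.58. Pamr1 rose by 1.96 ± 0.32, 2210407C18Rik by 1.84 ± 0.29, and Cym, the protease chymosin, by 1.79 ± 0.23. Bmf, a pro-apoptotic BH3-only protein, rose by 1.61 ± 0.15 (adjusted p = 8.65e-05). Edn1 (endothelin-1) rose by 1.54 ± 0.32 and Tubb3, a neuronal beta-tubulin, by 1.51 ± 0.25; Egfl6 and Ypel4 rose by 1.65 ± 0.40 and 1.59 ± 0.41 from dim means of 2.85 and 3.45, and Amer2 rose from 3.85 to 5.34 (adjusted p = 0.0162). Fibroblast markers in cultures, which should hold no fibroblasts, lay at 3.79 to 5.04, so means in that range or below are near background. This held for the lower mean of Bco2, Egfl6, Ypel4, Amer2, Cym, Tmem190, Tmem163, Tcf23 and Ugt2a3, and the sizes of their changes, and so their order, are not well measured.

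Of 19 measured RAS-MAPK output genes, 8 fell and none rose over all genes tested (13 fell adjusted over the list alone). The list mean was lower by 0.64 ± 0.14 (SE) and was lower in 5 of 5 lines. Besides Dusp6, the ephrin receptor Epha2 fell by 1.17 ± 0.17, and the Ras pathway inhibitors Spry2 and Spry4 fell by 1.07 ± 0.16 and 1.10 ± 0.23. Myc, a transcription factor of growth genes, fell by 0.68 ± 0.18 (adjusted p = 0.0370). The camera test gave an adjusted p of 1.65e-09 with the preset correlation and adjusted p = 0.224 with an estimated correlation; the exact permutation of the list mean within lines gave an adjusted p of 0.00252. Of 6 EGF receptor ligands, 4 fell (4 adjusted over the list alone): Tgfa by 0.96 ± 0.13, Btc by 1.13 ± 0.20, Hbegf by 1.06 ± 0.22, and Ereg. The list's adjusted p was 2.82e-05, and adjusted p = 0.224 with an estimated correlation (0.00630 by exact permutation).

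Cholesterol synthesis was the list with the lowest p. Of its 20 measured genes, 16 fell and none rose (17 fell adjusted over the list alone), with a list mean lower by 0.66 ± 0.10 (SE) and lower in 5 of 5 lines. Idi1, which isomerizes the isoprenoid building block, fell by 1.39 ± 0.17, Msmo1 by 1.24 ± 0.17, Cyp51 by 0.93 ± 0.14 and Fdft1, squalene synthase, by 0.86 ± 0.14. The camera adjusted p was 9.82e-17 with the preset correlation, adjusted p = 0.224 with an estimated correlation, and 0.00252 by exact permutation.

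In the pathways that the study chose on these samples, 4 of 7 hexosamine pathway genes fell (4 fell and 1 rose adjusted over the list alone, which is not independent evidence). Gfpt1, the rate-limiting enzyme of this pathway, fell by 0.56 ± 0.09 (adjusted p = 0.00336), Uap1 by 0.43 ± 0.09, Pgm3 by 0.43 ± 0.11 and Gnpnat1 by 0.32 ± 0.08. The list's camera adjusted p was 0.0367, with adjusted p = 0.271 with an estimated correlation and 0.00252 by exact permutation. Of 5 non-oxidative pentose phosphate genes, 1 fell (2 adjusted over the list alone): Rpia, ribose-5-phosphate isomerase, by 0.64 ± 0.09 (adjusted p = 0.00142). Rpe changed by -0.07 ± 0.09 and Tkt by 0.13 ± 0.15, neither of which passed. That list did not pass camera (adjusted p = 0.0877) and passed the exact permutation (adjusted p = 0.00900). Of 16 glycolysis genes 1 fell (1 adjusted over the list alone), Hk1 by 0.38 ± 0.09 (adjusted p = 0.0209). The glucose transporter Slc2a1 differed by -0.61 ± 0.24 (adjusted p = 0.143), Ldha by -0.26 ± 0.11 and Hk2 by -0.23 ± 0.15, and the glycolysis list did not pass (adjusted p = 0.105). Nras differed by 0.10 ± 0.08 and did not pass.

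Other biosynthesis and growth lists were called lower off dox by camera. Ribosome biogenesis had 5 of 20 genes that fell (11 adjusted over the list alone), among them Nolc1 by 0.49 ± 0.08 and Mybbp1a by 0.44 ± 0.10. Serine and one-carbon synthesis had 3 of 9 (7 over the list alone), with Psat1 lower by 0.62 ± 0.12 and the mitochondrial enzyme Mthfd2 by 0.73 ± 0.14. Pyrimidine synthesis had 4 of 14 that fell and 1 that rose (8 and 1 over the list alone). Rrm2, a subunit of ribonucleotide reductase, fell by 1.12 ± 0.19, and Cad, the first enzyme of the pathway, by 0.52 ± 0.09. DNA replication had 5 of 21 (10 over the list alone), with the cyclins Ccne1 and Ccne2 lower by 0.87 ± 0.24 and 0.70 ± 0.18, and the list mean was higher in 1 of 5 lines. The ATF4 targets had 2 of 10 that fell (2 over the list alone), Cth by 0.79 ± 0.16 and the asparagine synthetase gene Asns by 0.49 ± 0.13. With an estimated correlation the lists of ribosome biogenesis, serine, pyrimidine and ATF4 genes had adjusted p = 0.224 each, and DNA replication had adjusted p = 0.461. By exact permutation these lists had adjusted p from 0.00252 to 0.0405. The mitosis list was also called lower by camera (1 of 21 fell, Birc5 by 0.36 ± 0.10; 6 over the list alone), but had adjusted p = 0.490 with an estimated correlation and 0.113 by exact permutation.

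The epithelial list was called lower, with 4 of 12 genes that fell (5 over the list alone): the tight junction gene Cldn7 by 0.90 ± 0.15 and the keratins Krt7, Krt8 and Krt18 by 0.44, 0.26 and 0.26. Their adjusted p was 0.00134, and adjusted p = 0.290 with an estimated correlation (0.0183 by exact permutation). The lysosome and autophagy list was called higher, with 3 of 18 genes that rose and 1 that fell (5 and 1 over the list alone). Gabarapl1 and Map1lc3b, which build autophagosomes, rose by 0.45 ± 0.06 and 0.27 ± 0.07, and the sialidase gene Neu1 fell by 0.36 ± 0.10. The list's adjusted p was 0.00934, and adjusted p = 0.461 with an estimated correlation (0.0242 by exact permutation). Of 11 genes of the BCL2 family 2 rose (3 rose and 1 fell over the list alone), Bmf and Bcl2l11, which codes for BIM, the latter by 0.73 ± 0.15. That list did not pass camera (adjusted p = 0.271) and passed the exact permutation (adjusted p = 0.0412).

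The fibroblast list was called higher off dox by camera, by 0.37 ± 0.16 (SE) and in 5 of 5 lines, with none of 10 genes past the threshold (none over the list alone); its adjusted p was 0.00756, and adjusted p = 0.490 with an estimated correlation (0.0865 by exact permutation). The pericyte and smooth muscle list was higher by 0.34 ± 0.13 (SE), with 1 of 7 genes that rose (1 over the list alone), Acta2 by 0.61 ± 0.16; its adjusted p was 0.0255, and adjusted p = 0.461 with an estimated correlation (0.0586 by exact permutation). The macrophage list differed by 0.06 ± 0.21 and the endothelial list by 0.14 ± 0.11, neither called. Acinar markers varied most between tumors, with list means from 3.80 to 10.74 among the 9 tumors off dox and from 5.88 to 10.15 among the 10 on dox. The difference of the acinar list was -1.58 ± 1.15 (SE), not called (adjusted p = 0.172). The ratio of the 3'-end to the 5'-end probe sets of beta-actin was higher by 0.08 log2 units off dox (exact permutation within lines p = 0.00489, adjusted p = 0.0293; over all tumors p = 0.00514, adjusted p = 0.0309). The same ratio of Gapdh differed by -0.02 (p = 0.443 within lines, 0.535 over all tumors). The beta-actin shift was present in the same tumors as every gene group above.

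**Figure D1:**
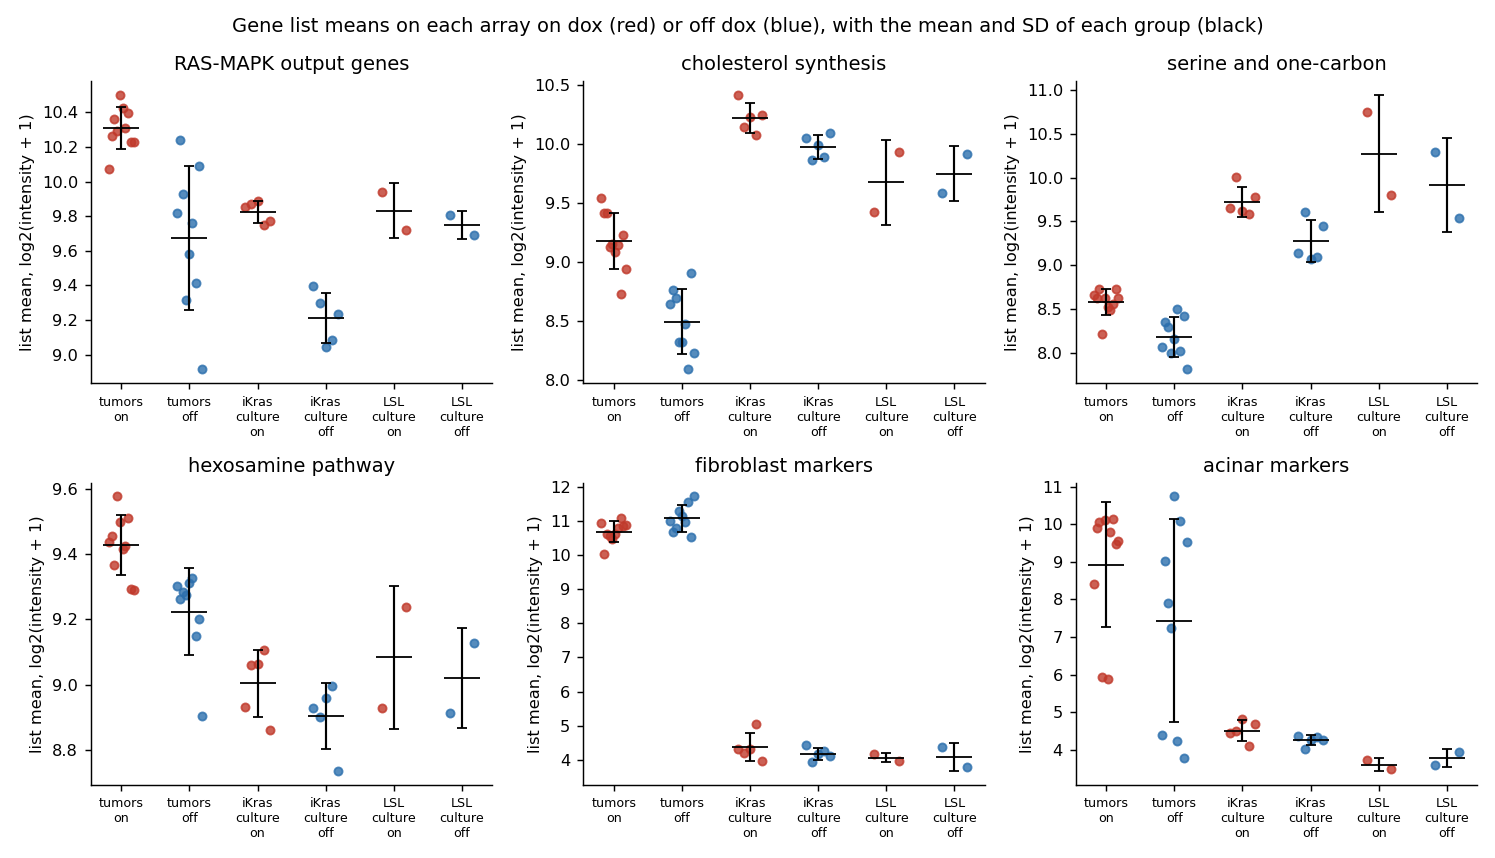
Each point is the mean log2(intensity + 1) of the genes of a list on 1 array, red on dox and blue off dox, for tumors, iKras cultures and LSL cultures; black bars give the mean and SD of each group, and the vertical axes differ between panels and do not start at 0. The RAS-MAPK list had a mean of 10.31 in the 10 tumors on dox against 9.67 in the 9 off dox, fibroblast markers lay above 10 in every tumor and between 3.79 and 5.04 in cultures, and acinar markers ranged from 3.80 to 10.74 among tumors off dox.

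With 1 mean per line and dox group limma called 0 genes (3287 at an unadjusted p under 0.05), although all 1163 genes kept their sign, 1161 of them stayed at an unadjusted p under 0.05, and their median size was 0.526 with a median SE of 0.116, against 0.524 and 0.114 over single tumors. The count was 127 with the beta-actin ratio as a covariate, 697 with a host cell marker score and 511 without line as a block, with all 1163 signs kept in each, median sizes of 0.522, 0.488 and 0.522 and median SEs of 0.155, 0.115 and 0.145, while it was 1783 without dim genes, 1807 with array weights and 1885 in 1 fit of all arrays. It was 639, 213, 442 and 590 without iKras1, iKras3, iKras4 and iKras5, and 754 without the second off-dox tumor of iKras4, and no named gene was called in the opposite direction in any fit.

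The second comparison asked which changes occurred in the tumor cells alone, in culture. After 24 h without dox, the MAPK feedback genes Dusp6 and Spry4 and the ETS factor Etv4 fell, and the YAP target Ccn1, the growth factor Tgfb2 and the pro-death genes Bmf and Bcl2l11 rose. Dusp6 fell by 1.15 ± 0.10 (SE) in all 5 lines, from 11.80 ± 0.22 to 10.65 ± 0.26 (SD, n = 5 each; limma adjusted p = 0.0127). Of 18193 genes, 187 rose and 126 fell, all 313 with the same sign in every line; 41 rose and 26 fell at least 2-fold.

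Among the largest falls were those of Hpcal4, a neuronal calcium sensor (by 2.61 ± 0.31, limma adjusted p = 0.0238), and of Etv4, an ETS transcription factor downstream of ERK (by 2.47 ± 0.40). Lratd1 fell by 2.13 ± 0.23, E330021D16Rik by 2.06 ± 0.28 and Ivl by 1.88 ± 0.17. Tmem174, Tmem63c and Tm4sf20 fell by 1.68 to 1.77. Spry4 fell by 1.67 ± 0.13 and the sialyltransferase gene St3gal6 by 1.46 ± 0.11. Ccn4, a secreted matricellular protein, rose by 3.32 ± 0.40 (limma adjusted p = 0.0238), from a dim level that varied widely between the cultures on dox, at 2.88 ± 2.04 (SD, n = 5). Edn1 rose by 2.84 ± 0.38, Bco2 by 2.43 ± 0.38 and the basal keratin Krt14 by 2.20 ± 0.35. The growth factor gene Tgfb2 rose by 1.98 ± 0.23, the metalloprotease inhibitor gene Timp3 by 1.95 ± 0.22 and the chemokine gene Ccl9 by 1.95 ± 0.27. The small heat shock protein gene Cryab, the protease gene Tll1 and 4930528A17Rik rose by 1.60 to 2.11. The lower mean was near background, at 5.04 or below, for Ccn4, Edn1, Bco2, Krt14, Tll1, 4930528A17Rik, Hpcal4, E330021D16Rik, Tmem174, Tmem63c and Tm4sf20, whose sizes and order are not well measured.

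RAS-MAPK output had 7 of 19 genes that fell and none that rose (14 fell and 1 rose adjusted over the list alone), and a list mean lower by 0.61 ± 0.06 (SE) in 5 of 5 lines. Besides Spry4 and Dusp6, Dusp5 fell by 1.26 ± 0.11 and Fosl1, an AP-1 factor, by 1.11 ± 0.13. Of 6 EGF receptor ligands 3 fell (4 fell and 1 rose over the list alone): Btc by 1.15 ± 0.09, Ereg by 0.84 ± 0.07 and Tgfa by 0.63 ± 0.08. Of 9 serine and one-carbon genes 3 fell (9 over the list alone), Psat1, Psph and Mthfd1l by 0.50, 0.53 and 0.45. These 3 lists had camera adjusted p of 3.77e-10, 2.64e-04 and 1.09e-08, and adjusted p = 0.192 each with an estimated correlation. Cholesterol synthesis had 2 of 20 that fell (6 over the list alone), Lss by 0.78 ± 0.12 and Insig1 by 0.45 ± 0.07; its adjusted p was 3.22e-07, and adjusted p = 0.216 with an estimated correlation.

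Of 10 targets of the YAP coactivator 3 rose (6 over the list alone): Ccn1 by 1.51 ± 0.14, Amotl2 by 0.83 ± 0.07 and Ajuba by 0.47 ± 0.07. The list was called higher, with adjusted p = 1.68e-06, and adjusted p = 0.203 with an estimated correlation. Of 12 p53 targets 3 rose (4 rose and 1 fell over the list alone), Plk2 by 1.45 ± 0.10, Trp53inp1 by 1.35 ± 0.14 and Pmaip1, which codes for the BH3-only protein NOXA, by 1.00 ± 0.15; the list's adjusted p was 0.0215, and adjusted p = 0.222 with an estimated correlation. Growth factor receptor genes were higher as a list (by 0.27, none of 13 past the threshold, 3 over the list alone), with adjusted p = 0.0111, and adjusted p = 0.216 with an estimated correlation. Bcl2l11 and Bmf rose by 0.85 ± 0.10 and 0.97 ± 0.13, the 2 of 11 BCL2 family genes that passed (2 over the list alone), in a list that did not pass camera (adjusted p = 0.223). Ribosome biogenesis was called lower with 0 of 20 genes past the threshold (5 lower over the list alone), as were fatty acid synthesis (0 of 10, 3 over the list alone), purine synthesis (0 of 10, 3 over the list alone) and pyrimidine synthesis (0 of 14; 2 lower and 1 higher over the list alone). Lists called lower with 1 gene that fell were endoplasmic reticulum chaperones (of 13, 3 over the list alone; Manf by 0.37 ± 0.06), DNA replication (of 21, 1 over the list alone; Ccne1 by 0.48 ± 0.07), ATF4 targets (of 10, 2 over the list alone; Asns by 0.49 ± 0.07) and NRF2 targets (of 9, 3 over the list alone; Gclc by 0.39 ± 0.06). These 8 lists had adjusted p from 7.71e-07 to 0.0244. With an estimated correlation their adjusted p lay between 0.222 and 0.529.

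Of the pathways chosen by the study, glycolysis was called lower in culture (1 of 16 fell, 4 over the list alone, which is not independent evidence), with adjusted p = 0.0221, and adjusted p = 0.222 with an estimated correlation. Slc2a1, the glucose transporter GLUT1, fell by 0.72 ± 0.07 (limma adjusted p = 0.0170). Hk2 differed by -0.44 ± 0.08 (limma adjusted p = 0.0571), Hk1 by -0.36 ± 0.08 and Ldha by -0.06 ± 0.06, none of which passed. The hexosamine list had 0 of 7 genes past the threshold (2 lower over the list alone) and was not called by camera (adjusted p = 0.223), with Gfpt1 at -0.28 ± 0.06 (limma adjusted p = 0.0835). Fry gave this list an adjusted p of 0.00272 in iKras cultures, but also 0.0205 in LSL cultures. The non-oxidative pentose phosphate list had 0 of 5 (1 lower over the list alone; adjusted p = 0.884), with Rpia at -0.41 ± 0.08 (limma adjusted p = 0.0691) and Rpe at 0.10 ± 0.07. Myc differed by -0.15 ± 0.10 and Nras by 0.01 ± 0.06.

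The culture count fell whichever line was left out. Limma called 0 genes without iKras1, iKras2, iKras3 or iKras4, and 25 without iKras5. At an unadjusted p under 0.05 there were 2563, 2664, 2650 and 2491 genes without iKras1 to iKras4, against 3013 with all lines. The culture count was 52 without either LSL line, which only lent its spread. It was 6 without line as a block, 88 with every probe set and 109 with the mean of a gene's probe sets, but 716 with an offset of 32, 1255 without dim genes and 1449 with the trend and robust options.

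The LSL cultures addressed whether dox itself changed expression where Kras did not depend on it. A single gene passed, Ifi202b, an interferon-inducible gene, which was higher off dox by 2.33 ± 0.14 (limma adjusted p = 0.0381) from a dim level of 1.77 ± 0.31 to 4.10 ± 0.49 (SD, n = 2 each). Both means were near background, so the size of this change is not well measured. At an unadjusted p under 0.05 there were 1244 genes, against 910 expected by chance. Of the fixed genes, none of which passed, Myc differed by -0.35 ± 0.15, Gfpt1 by -0.23 ± 0.09, Dusp6 by -0.19 ± 0.15, Rpia by -0.16 ± 0.13, Slc2a1 by -0.12 ± 0.11, Hk2 by -0.11 ± 0.12, Hk1 by -0.08 ± 0.13, Nras by -0.04 ± 0.09, Ldha by 0.01 ± 0.09 and Rpe by 0.06 ± 0.11. The RAS-MAPK list mean differed by -0.08 ± 0.10 (SE), with -0.14 in LSL-Kras1 and -0.03 in LSL-Kras2. In list tests added after the data were seen, with members also chosen after their values were seen, ATF4 targets were called lower (list mean -0.64, Asns at -0.97 ± 0.11, 0 of 10 past the threshold and 6 lower over the list alone), as were serine and one-carbon genes (list mean -0.36, Psph at -0.63 ± 0.12, 0 of 9 and 5 lower over the list alone). DNA replication and ribosome biogenesis were called higher, by 0.22 and 0.14, with 0 of 21 and 0 of 20 genes past the threshold. All 4 had adjusted p = 0.693 with an estimated correlation. Ifi202b did not pass with an offset of 32 (adjusted p = 0.504), without line as a block (0.208) or without iKras1, iKras3, iKras4 or iKras5 (0.0697 to 0.123). The count was 0 without iKras1 or iKras3, 4 without iKras2, 31 without LSL-Kras1 and 44 without LSL-Kras2, the line whose dox labels disagree, where the lone pair left was assumed to vary like the other lines; it was 92 in 1 fit of all arrays and 0 to 12 in the other fits.

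Tested against each other, the responses of iKras and LSL cultures differed for 0 genes in limma (2048 at an unadjusted p under 0.05; lowest adjusted p = 0.0801). Of the fixed genes, Dusp6 differed by -0.97 ± 0.18 (limma adjusted p = 0.219), Slc2a1 by -0.61 ± 0.13, Hk2 by -0.33 ± 0.15, Hk1 by -0.28 ± 0.16, Rpia by -0.25 ± 0.15, Gfpt1 by -0.05 ± 0.11 and Myc by 0.20 ± 0.18, and Ldha, Nras and Rpe by -0.06 to 0.05. As a list, RAS-MAPK output differed by -0.53 ± 0.11 (SE), with 0 of 19 genes past the threshold and 8 lower over the list alone; Spry4, chosen after its values were seen, differed by -1.77 ± 0.24. EGF receptor ligands differed by -0.35, cholesterol synthesis by -0.32, ribosome biogenesis by -0.36, DNA replication by -0.35 and pyrimidine synthesis by -0.27, while YAP targets differed by 0.52 and ATF4 targets by 0.41. These 8 lists were called by camera, in tests added after the data were seen, and had adjusted p from 0.407 to 0.482 with an estimated correlation. For the 313 genes called in iKras cultures, at a median size of 0.70 there, the median response signed by that direction was -0.01 in LSL cultures and 0.45 in tumors. The count was 15 without LSL-Kras1, 5 without line as a block, 2 with the mean of probe sets, 56 without dim genes and 176 with the trend and robust options.

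**Figure D2:**
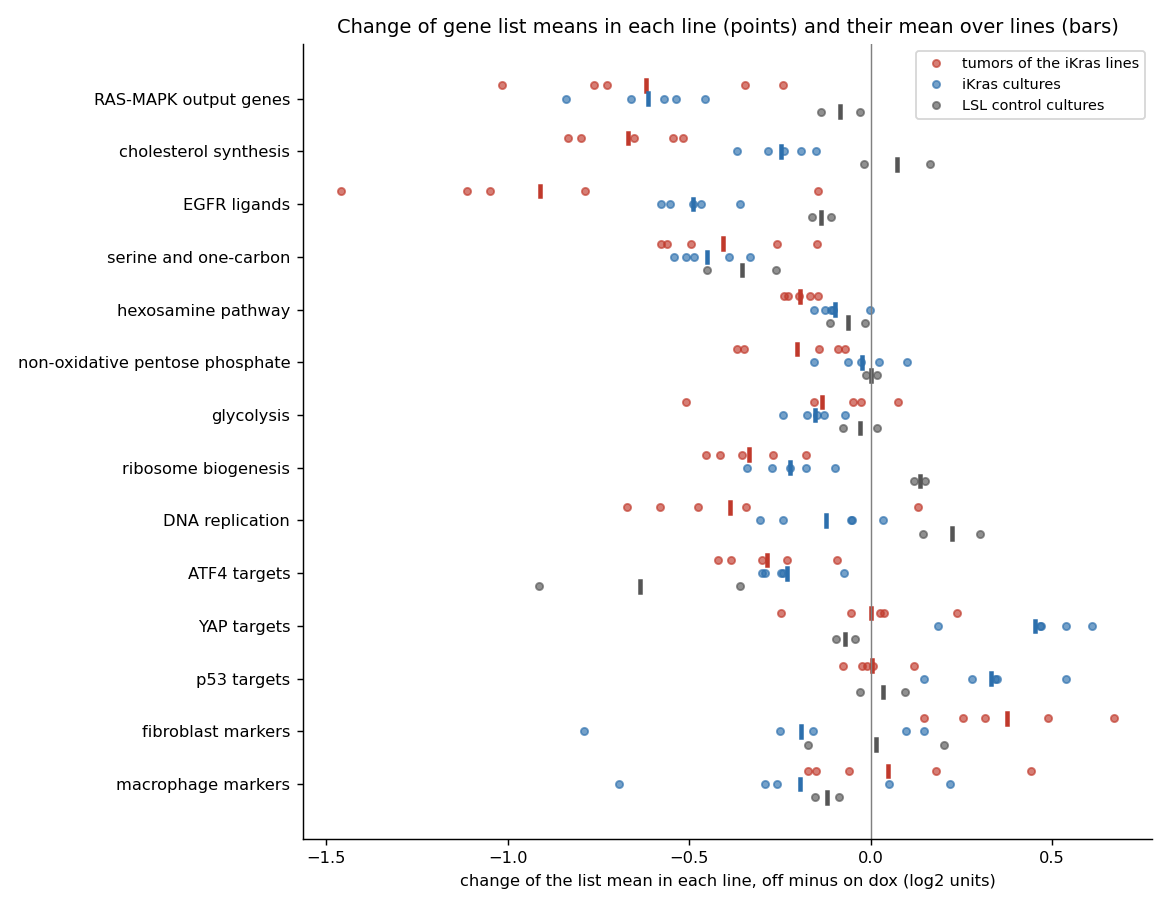
Each point is the change of a gene list's mean in 1 line, off minus on dox in log2 units, and each bar is the mean over lines, for tumors (red), iKras cultures (blue) and LSL cultures (grey). The RAS-MAPK list was lower in 5 of 5 lines in tumors and in iKras cultures, YAP targets were higher in 5 of 5 iKras cultures, and ATF4 targets changed by -0.91 and -0.36 in the LSL cultures.

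The next comparison asked how far the response in tumors matched that in culture. Across all genes the fitted changes had a Pearson r of 0.222 and a Spearman rho of 0.258; genes are not independent replicates, and no p is given. With dim genes removed r was 0.466. Of the 313 genes called in culture, 281 (89.8%) had the same sign in tumors and 153 (48.9%) in LSL cultures. Passing in both were 81 genes that rose and 73 that fell, where independent lists of these lengths would share 5.95 and 4.04. Among them were Ivl, Spry4, Dusp5, Dusp6, Ereg and Btc, which fell, and Bco2, Edn1, Krt14, Bmf and Bcl2l11, which rose. Ccl9 alone passed in opposite directions, at -0.87 ± 0.18 in tumors and 1.95 ± 0.27 in cultures.

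**Figure D3:**
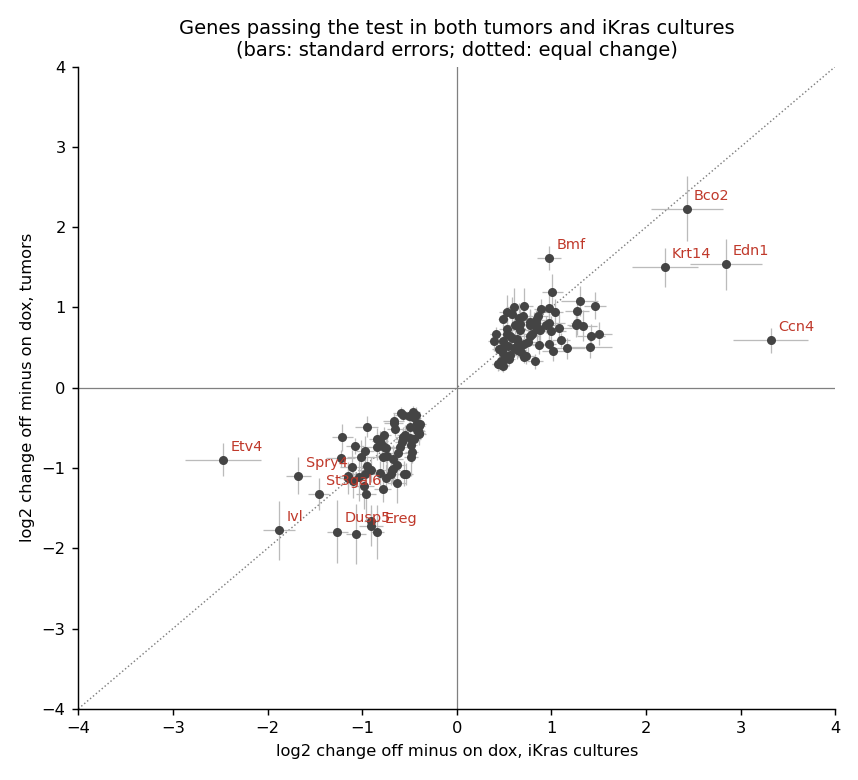
Each point is 1 of the 81 genes that rose or the 73 that fell by the limma test in both tumors (vertical axis) and iKras cultures (horizontal axis), as log2 change off minus on dox with standard errors; the dotted line marks equal change. Bco2 and Ivl lie near the line, Ccn4 (3.32 in culture) lies far below it and Bmf (1.61 in tumors) above it.

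The difference between the tumor and the culture response passed for 10 genes, 2 higher and 8 lower in the tumor response. The largest were Ccl9 (-2.83 ± 0.33) and Ccn4 (-2.73 ± 0.32, both limma adjusted p = 0.000673), then Dusp1, an early-response phosphatase gene (-1.60 ± 0.28), Plk2 (-1.56 ± 0.20) and Igfbp7 (-0.87 ± 0.12). On the other side were the tight junction gene Cldn2 (1.09 ± 0.15) and Podxl, an apical sialomucin gene (0.77 ± 0.11). Plk2 has 2 probe sets, of which only 1, the one tested, had a negative difference, and the other did not pass. Ccn4 illustrates a gene whose level in tumors on dox, 7.32 ± 0.38 (SD, n = 10), was already far above that in culture, 2.88 ± 2.04 (SD, n = 5), which is near background, so the size of its difference is not well measured. Levels on dox were also higher in tumors for Ccl9 (10.24 against 5.41), Dusp1 (10.49 against 8.13), Igfbp7 (13.73 against 11.46) and Cldn2 (12.00 against 9.98). Plk2 (9.07 against 8.90) and Podxl (10.38 against 9.88) were closer. Whether host cells in the tumors supplied part of these levels was not tested. In list tests added after the data were seen, cholesterol synthesis differed by -0.41 (0 of 20 past the threshold, 7 over the list alone). YAP targets differed by -0.47, with 1 of 10 past the threshold (4 over the list alone). With an estimated correlation these 2 lists had adjusted p = 0.444 and adjusted p = 0.0906. The count was 4 without iKras2, 2 without iKras3, 6 with the mean of probe sets, 23 without dim genes, 19 with the trend and robust options and 30 with array weights. Limma called 0 genes without line as a block (866 at an unadjusted p under 0.05), and 0 with 1 mean per line and dox group (1779).

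The last comparison set tumors on dox against cultures on dox and gives the context of the host cell markers. Here 3386 genes were higher and 5083 lower in tumors, with a median shift over all genes of -0.17. Collagens, macrophage genes and acinar genes were among those higher in tumors: Lyz1 by 10.98 ± 0.39, Col1a1 by 10.82 ± 0.29, C1qa, a complement gene of macrophages, by 9.77 ± 0.26, Cpa1, a pancreatic carboxypeptidase, by 9.60 ± 1.80 and Col3a1 by 9.27 ± 0.28. Their means in cultures, 1.31 to 4.53, were at or near background, so the sizes and order of these differences depend on the background and the offset and are not measured ratios. All 10 fibroblast, 10 macrophage and 10 endothelial markers were higher, and their list means differed by 6.32, 5.16 and 2.87 (adjusted p = 0.00136, 0.0228 and 0.0104 with an estimated correlation), again from culture means near background (4.37, 5.13 and 4.63). Of 15 hypoxia targets 13 were higher (13 over the list alone), with adjusted p = 0.0846 with an estimated correlation. Lower in tumors were all 21 mitosis genes (adjusted p = 0.0733 with an estimated correlation), all 20 ribosome biogenesis genes (adjusted p = 0.0152) and 23 of 25 respiratory chain genes (24 over the list alone, adjusted p = 0.0393). Tumor arrays also hold host and acinar RNA, so these values do not show a lower level in the tumor cells themselves. Among the genes lowest in tumors against cultures were Tmigd1 (-4.79 ± 0.27), Cst9 (-4.44 ± 0.49), the chemokine gene Ccl20 (-4.18 ± 0.59), Chtf18 (-4.02 ± 0.50) and Aldh3a1 (-4.00 ± 0.31), of which Cst9, Ccl20 and Chtf18 were near background in tumors (2.76, 4.30 and 3.81). The count was 17849 with every probe set tested.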

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

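Of the weighed explanations, those on the share of tumor cells and on acinar tissue for RAS-MAPK and cholesterol genes, and that on separate preparation, were written before their results were seen. The tests on fibroblast markers, on doxycycline itself and on RNA quality were chosen after the result was seen, so they are tests and not predictions.

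RAS-MAPK output and cholesterol synthesis genes were lower in tumors off dox by 0.637 and 0.658 log2 units, which a lower share of tumor cells, acinar tissue or poorer RNA might produce. With the host cell marker score as a covariate the differences were -0.491 (95% interval -0.702 to -0.279) and -0.568, with the acinar score -0.694 and -0.698, and with the beta-actin ratio -0.654 (-1.10 to -0.212) and -0.676, so none of these 3 removed them. The host score averages 3 marker lists, and 1 slope was fitted over tumors on and off dox. The off-dox tumor with the highest fibroblast mean (11.72) had the lowest RAS-MAPK mean (8.92). A part that comes from a lower share of tumor cells therefore stays open. With the beta-actin ratio the gene count fell from 1163 to 127 because the median SE rose from 0.114 to 0.155, while the median size went from 0.524 to 0.522. Fibroblast markers were higher, relative to the mean of macrophage and endothelial markers, by 0.269 (0.121 to 0.417). That argues only against an equal rise of all host cells. Fewer tumor cells with more fibroblasts would give the same difference, so a smaller share of tumor cells and a change in fibroblasts both stay open. Loss of the transgene stays open as the biological explanation, as does doxycycline itself, since no LSL tumors were profiled. RNA quality stays open for single genes.

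Serine and one-carbon genes were lower off dox in iKras cultures by 0.451 log2 units, but also in LSL cultures, by 0.355 (95% interval -0.534 to -0.176), so that the responses differed by -0.0964 (-0.308 to 0.116). That fits an effect of doxycycline itself on these genes, and ATF4 targets changed by -0.636 in LSL cultures against -0.230 in iKras cultures. RAS-MAPK output genes differed by -0.529 (-0.820 to -0.238) between the iKras and LSL responses, which argues against doxycycline itself as the cause of their fall. The LSL response rests on 2 lines, and the dox labels of 1 of them, LSL-Kras2, disagree. The list values were not refitted without it. In LSL-Kras1 alone RAS-MAPK output changed by -0.138, serine and one-carbon genes by -0.450 and ATF4 targets by -0.914. A part of the serine and one-carbon fall that depends on the transgene stays open.

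On the LSL arrays the 18S ribosomal RNA probe sets, which no comparison uses, were brighter than on iKras culture arrays by 7.63 log2 units, and the poly-A spikes, bacterial transcripts added to the RNA, by 4.60; all 4 LSL arrays lay above all 10 iKras culture arrays in both. The hybridization spikes, added later, differed by 0.206. The spikes hold no mouse RNA, so this fits a separate preparation of the LSL samples. Changes within a line are compared on arrays of the same kind, whereas levels of iKras and LSL lines cannot be told from the preparation. No biological explanation was tested.

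Random splits of the same arrays showed how many calls arise with no real grouping. For the tumor genes (1163, with a highest other of 1, and of 3 for splits within lines) 1 split, the real one, reached the count in each set. That argues against chance only if the tumors of a line are independent, which the labels do not say. With 1 mean per line and dox group the tumor gene count was 0. The real count was also the highest for the tumor minus culture genes (10 against 3) and the genes of tumors against cultures (8469 against 2011). Those splits did not keep lines together and exchanged tumors, which hold host tissue, with cultures, so they cannot decide on chance. With 1 mean per line and dox group the tumor minus culture count was 0. For the number of tumor lists called by camera chance cannot be excluded. The 14 lists called were reached by 12 of 51 splits, up to 25, and by 10 of 50 splits within lines, up to 19. These splits bear on that number and not on single lists. By the exact permutation within lines, which also takes tumors as independent, 15 of 49 lists passed. The cultures are paired by line, and the 16 splits that part every pair were too few (313 genes against 1, 16 lists against 9). The other 84 of 100 splits did not part every pair, and gave up to 3 genes and 13 lists.

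A single sample lay far from the rest of its group, as gap over range, in 19 of 316 groups of values, where chance gives 15.8, about 1 in 20 groups. The second off-dox tumor of iKras5 was the lowest for Agr2 (0.582), Ivl (0.652) and the hexosamine list (0.580) and the highest for endothelial markers (0.501). Single tumors stood apart for Agr2 on dox (0.647), Amer2 (0.501) and Ugt2a3 (0.652) off dox. Among pathway lists in tumors they did so for the oxidative pentose phosphate list (0.571), mitochondrial ribosome (0.539), serine and one-carbon synthesis (0.530) and EGF receptor ligands (0.470). Among marker lists they did so for neutrophil (0.588), adipocyte (0.626), skeletal muscle (0.495) and mesothelial (0.653) genes. Single cultures stood apart for ribosome biogenesis (0.744), the BCL2 family (0.857), mesenchymal genes (0.784) and natural killer cell genes (0.735).

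Differences between the tumor and the culture response were tested directly. They passed for Ccl9 (-2.83), Ccn4 (-2.73), Dusp1 (-1.60), Plk2 (-1.56), Igfbp7 (-0.871), Podxl (0.775) and Cldn2 (1.09), all brighter in tumors on dox than in cultures on dox. The same test on lists passed for cholesterol synthesis (-0.412), DNA replication (-0.245), mitosis (-0.288), p53 targets (-0.328), YAP targets (-0.471) and epithelial genes (-0.269), and for fibroblast (0.558) and pericyte and smooth muscle genes (0.504). The last 2 values do not compare responses of these cells: cultures should hold no such cells, and fibroblast markers lay at 4.37 on and 4.18 off dox there, near background, against 10.69 and 11.08 in tumors. Pericyte and smooth muscle markers lay at 5.42 and 5.25 in cultures. Only 0.367 and 0.337 of the differences came from the tumors, and the rest came from cultures, where these markers were dim. None of these lists passed with an estimated correlation (lowest adjusted p = 0.0906).

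The response of iKras cultures differed from that of LSL cultures for RAS-MAPK output (-0.529), pyrimidine synthesis (-0.271), cholesterol synthesis (-0.319), ribosome biogenesis (-0.358), DNA replication (-0.346), EGF receptor ligands (-0.354), ATF4 targets (0.406) and YAP targets (0.523), by camera with the preset correlation. With an estimated correlation the lowest adjusted p was 0.407, and the 95% interval of the ATF4 difference was -0.0109 to 0.823. For pyrimidine, cholesterol, ribosome biogenesis and DNA replication genes, part of the difference was a rise in LSL cultures off dox.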

How the results depend on the processing

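Directions of called genes were stable and calls were not. The alternatives reused the same arrays. In tumors and iKras cultures the largest changes were named only with the same sign in every line, so leaving out a line could not reverse them. No named gene was called in the opposite direction under any alternative, and 1 list was: macrophage markers in tumors, not called without a covariate, were lower by -0.201 with the host cell score, which is built in part from those markers. For genes named in tumors, 7237 of 8262 values kept direction and call, 749 lost the call, 127 gained it and 149 were uncalled values of changed sign; in cultures these were 3198, 455, 142 and 34 of 3829. The difference between tumor and culture responses kept 220 of 255 values, the LSL response 177 of 187, the iKras minus LSL difference 153 of 160, and tumors against cultures all 158. Tumor lists kept 1584 of 1754 values and culture lists 518 of 578, with 71 and 20 uncalled values of changed sign. Dropping the 40% dimmest genes, those nearest to background, left 10916 genes to test and raised 5 counts of genes; what part of that came from fewer tests was not tested. Centring, renewed quantile normalization and line as a random block moved no count by over 1.5 times.

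Without the replicate block, that is without the pairing by line, counts were 511 genes in tumors, 6 in cultures, 9 in LSL cultures, 5 for iKras minus LSL and 0 for tumor minus culture responses; it moved no other count by over 1.5 times. With 1 mean per line they were 0 in tumors and 0 for tumor minus culture. Without dim genes they were 1783, 1255, 9, 56 and 23 in the order above, with a correlation of responses of 0.466. With an offset of 32 they were 716 in cultures and 0 in LSL cultures, with a correlation of 0.410. With the mean of probe sets they were 109, 3, 2 and 6 from cultures to tumor minus culture; with every probe set 88 in cultures, 0 in LSL cultures and 17849 for tumors against cultures, where more probe sets are tested. Trend and robust options gave 1449, 12, 176 and 19, and array weights 1807 in tumors, 2 in LSL cultures and 30 for tumor minus culture. One fit of all arrays gave 1885 in tumors and 92 in LSL cultures, and iKras cultures alone gave 52. Covariates gave 697 genes in tumors with the host cell score and 127 with the beta-actin ratio, the latter chosen after the data were seen. With an estimated correlation camera called 0 lists in tumors and 0 in cultures (9 and 10 at an unadjusted p under 0.05). Fry called 16 lists in tumors and 21 in cultures. Unless stated, the cause was not tested.

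With 1 line or 1 tumor left out, the single tumors chosen after the data were seen, counts ranged from 213 to 1439 genes in tumors, 0 to 52 in cultures, 0 to 44 in LSL cultures, 0 to 15 for iKras minus LSL and 2 to 8 for tumor minus culture; the correlation ranged from 0.160 to 0.207. Fewer samples tend to lower such counts, but some counts rose. The rise to 1439 in tumors came from leaving out a tumor of iKras2. The LSL count also rose without either LSL line, and the iKras minus LSL count without LSL-Kras1. The causes were not tested.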

Other observations

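Of 17 measured cytokine and chemokine genes 4 fell and none rose in tumors off dox (5 adjusted over the list alone): Il6 by 1.12 ± 0.32 (SE), Il1b by 1.00 ± 0.23, Il33 by 0.76 ± 0.18 and Il1a by 0.47 ± 0.11. The list as a whole passed neither camera (adjusted p = 0.0515) nor the exact permutation (adjusted p = 0.0616), Il6 and Il1b were lower in 4 of 5 lines, and the neutrophil markers differed by -0.49 ± 0.40. Il33 also fell in iKras cultures, by 0.74 ± 0.11. Single genes fell in tumors in lists that did not pass camera: Plaur, the urokinase receptor, by 1.02 ± 0.16, Has2, a hyaluronan synthase, by 0.68 ± 0.19, Mgat5, which branches N-glycans, by 1.02 ± 0.16, and the p53 target Perp, a desmosome gene, by 1.08 ± 0.11. The N-glycan list of Mgat5 (camera adjusted p = 0.0522) was lower in 5 of 5 lines and passed the exact permutation (adjusted p = 0.00252). Elovl6, a fatty acid elongase, fell by 0.81 ± 0.15 and Idh3a of the citrate cycle by 0.43 ± 0.08. In glutamine use, Got1 and Slc1a5 fell by 0.51 ± 0.10 and 0.48 ± 0.13, and Mdh1 rose by 0.35 ± 0.07.

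Between the iKras lines 420 genes differed in culture by limma's F test with dox as a covariate (adjusted p under 0.05), 202 of them by more than 2 log2 units. The genes that follow were chosen after their values were seen, stand for no tested group, and are given as means of a line's arrays on and off dox. Cldn18, a tight junction gene of stomach, stood at 11.67, 5.50, 11.16, 10.50 and 7.29 in cultures of iKras1 to iKras5 and at 11.56, 5.47, 10.60, 10.06 and 8.07 in their tumors. Tm4sf4 was ordered alike in both settings, from 13.15 in iKras1 to 7.70 in iKras5 in culture and from 12.30 to 8.83 in tumors. Apob, an apolipoprotein gene, was highest in iKras5, at 12.36 in culture and 12.13 in tumors. Gkn2, a gastric mucosal gene, was higher in tumors of every line, from 11.09 to 13.51, than in its culture, from 5.47 to 9.27. The gastric mucin gene Muc5ac ranged from 5.24 to 10.59 in culture and from 4.73 to 6.37 in tumors, and was lower in tumors of 4 of 5 lines.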
